A study of Mus musculus with 9 samples.

How the data were processed

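Polyadenylated RNA of sorted embryonic knee cells was sequenced as bulk libraries prepared with the Nextera XT kit, per the labels' protocols. The submitters' processing notes name FastQC, STAR, Salmon, DESeq2 and the mouse build mm10, without versions or the role of each. Which reads were counted, over which gene models and with what strand setting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and near-identical genes may share reads.

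The deposited table holds a signal per gene and library, in normalized counts, for 54532 Ensembl mouse genes in 9 libraries (23956 genes had no read in any library). In each library 100% of values were whole multiples of the value of 1 read, to within 0.001 of a read. Dividing by it gave reads, with totals between 25199258 and 47079305 per library. If the authors rounded estimated counts before scaling, these are rounded estimates. The reporter sequences tdTomato and EGFP were not analysed here. Gene symbols, biotypes and 1-based coordinates came from GENCODE M21, which is built on GRCm38, the assembly that mm10 names. Of the deposited identifiers 54495 matched it and 37 did not.

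Samples were grouped by the sorted population named in their labels, with 3 libraries each from separate litters. Groups, the tests of the comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A correction for transcript length, and the tests of explanations in the closing section other than those of other splits, were added after the data were seen. Two-sided tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(normalized count + 1), so that fold changes of low genes are understated. Genes with a mean of at least 10 over the 9 libraries were tested (17764), all 9 libraries shared 1 estimate of the spread, and p values were adjusted by Benjamini and Hochberg over the genes of a comparison, with calls under 0.05. Genes were called higher or lower in double-positive cells than in both other populations where both comparisons passed in that direction. Pairs of replicate libraries differed by more than sampling noise (chi-square per degree of freedom of at least 46.6), so each counted as a separate sample.

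The 26 fixed gene lists covered joint interzone, cartilage, prehypertrophic and osteoblast, tendon and loose connective tissue genes, and markers of muscle, endothelial, blood and immune, erythroid, Schwann and neuronal, epidermal and pericyte cells. They also covered signaling pathways (BMP, Wnt, TGF-beta, hedgehog, FGF, retinoic acid), limb patterning factors, cell cycle phases, dissociation stress, the CREB and ATF family, glycolysis and hypoxia, mitochondrially encoded and ribosomal protein genes. Erg is in both the interzone and the endothelial list. Lists were tested against the other genes with camera at a preset correlation of 0.01 between genes and adjusted over the 26 lists of a comparison, and their members were also adjusted over the list alone. Camera called 17, 14 and 14 lists for double-positive against GFP-only, RFP-only against GFP-only and double-positive against RFP-only cells. With a correlation estimated from the residuals camera called 0, 0 and 1 of them, the last being cartilage, while 4, 4 and 4 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance in 1 direction, called 10, 17 and 5.

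The text names Creb5, Sox9, Gdf5, Prg4, Erg, Wnt9a and Col2a1 in each comparison. For each comparison and direction it adds the 5 genes with the largest change that passed, had a mean of at least 100 in the higher group and had 1 sign in all 3 litters, leaving out predicted genes. From each list it draws on up to 3 passing members with the smallest adjusted p in the main direction and 1 in the other. For double-positive cells it adds the 8 genes highest and 5 lowest relative to both other populations under the same conditions.

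The labels give each number as a separate litter collected together, so the numbers pair the libraries across populations. Deviations from the population means correlated between libraries of 1 litter with a median of 0.103 over 9 pairs (-0.0353 to 0.149) and between libraries of different litters with a median of -0.0409 over 18 pairs (-0.146 to 0.0915). Deviations from a population's mean cancel over its litters, so a positive correlation within litters lowers that between litters, and the contrast of these medians is partly arithmetic. The consensus correlation within litters, from the fit with litter as a random block, was 0.0169. Litter as a block was run beside the planned fit without it. Other alternatives changed the pseudocount, the filter, the scaling (TMM, quantile, median of ratios), the weights and the variance prior, used 2 populations at a time, left out single libraries or litters, or ran edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, where edgeR called 1236, 3191 and 411 genes in the 3 comparisons. Where 1 litter was left out, or 1 library of a population, the libraries that remained were taken to vary like the other populations.

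The fits were tested on simulated reads for 17764 genes with known changes. For double-positive against GFP-only cells limma recovered 11.9% of genes changed 2-fold, 73.1% of genes changed 4-fold and 84.8% of genes changed 8-fold. For RFP-only against GFP-only cells these shares were 20.9%, 71.6% and 87.9%, and for double-positive against RFP-only cells 19.4%, 68.7% and 87.9%. Most changes of 2-fold were therefore missed in this simulation. It planted 200 changed genes in each of the double-positive and RFP-only groups and gave all libraries the same spread. More genes were called in the data, where the adjustment is then less strict, so these shares are no detection limit of the comparisons. Counting intervals and floors cover counting error only, since reads of 1 molecule cannot be told apart.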

Results

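RNA was sequenced from cells of developing mouse knees at embryonic stage E14.5, while the synovial joint forms between the cartilages of the future bones. The embryos carried a pair of fluorescent reporters. A tdTomato reporter at Creb5, which encodes a bZIP transcription factor, gave red fluorescence (RFP). An EGFP reporter at Sox9, the transcription factor that directs chondrocyte formation, gave green fluorescence (GFP). Flow cytometry divided the cells into GFP-only, RFP-only and double-positive populations. Each population was represented by 3 libraries, 1 from each of 3 independent litters (numbered 1, 2 and 5), for 9 libraries. By their name, the deposited values leave out the litters numbered between 2 and 5, for a reason not given in the sources used here. Recovered read totals lay between 25199258 and 47079305 per library.

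The study's title concerns Creb5 as a regulator of its own expression and of the gene program of the joint interzone, the layer of flattened cells where a joint forms. The comparisons ask how cells with both reporters differ from cells with either reporter alone. Values are deposited normalized counts, given as mean ± SD (n = 3 libraries per population), and log2 fold changes carry their standard error (SE). Across the 3 populations, 3050 of 17764 tested genes differed (limma F-test). That number was 1991 without the RFP-only library of litter 1 and 1938 without that of litter 5.

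**Figure D1:**
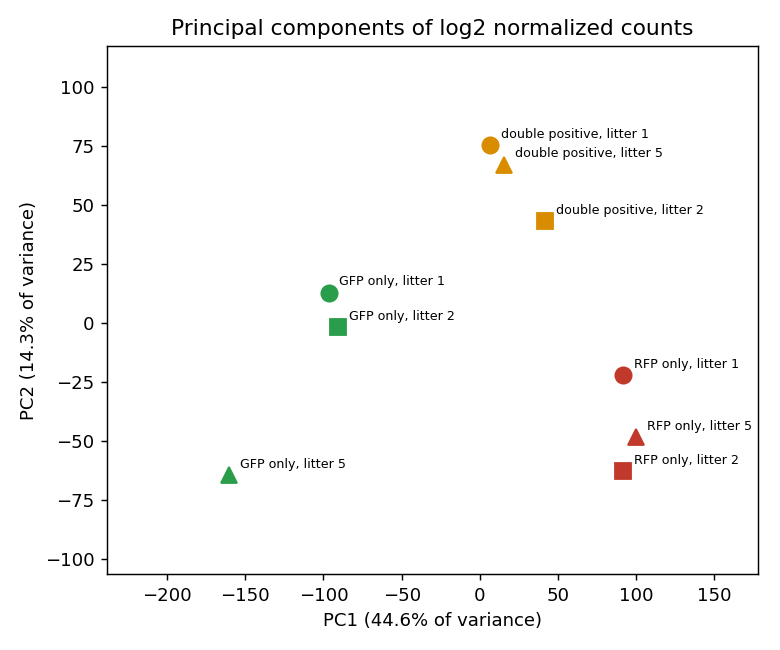
First and second principal components of log2 normalized counts of the tested genes, 1 point per library, with color for the population and marker shape for the litter. PC1 held 44.6% of the variance and PC2 14.3%, and the GFP-only library of litter 5 lay at a PC1 score of -160.3, apart from the other GFP-only libraries at -96.8 and -90.4.

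The host genes of the reporters set the sort, so their differences are no independent finding, and they were read first as a check of the labels. Creb5 (ENSMUSG00000053007, plus strand of chromosome 6, 53287270 to 53700376, GRCm38) had 203 ± 68.1 normalized counts in GFP-only cells, 3044 ± 333 in double-positive cells and 2959.8 ± 832 in RFP-only cells. Its log2 fold change was 3.95 ± 0.30 for double-positive against GFP-only cells (adjusted p = 0.000104) and 3.87 ± 0.30 for RFP-only against GFP-only cells (adjusted p = 1.42e-05), with 1 sign in all 3 litters. Between double-positive and RFP-only cells the Creb5 difference of 0.08 ± 0.30 did not pass (adjusted p = 0.984). Its sign turned without the double-positive library of litter 1 or the RFP-only library of litter 2, where it was -0.01 and -0.18 (adjusted p 0.951 to 0.999).

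Sox9 (ENSMUSG00000000567, plus strand of chromosome 11, 112782224 to 112787760, GRCm38) had 28910.0 ± 8025 normalized counts in GFP-only cells, 23474 ± 6622 in double-positive cells and 1618 ± 457 in RFP-only cells. It was lower in RFP-only than in GFP-only cells (-4.17 ± 0.30, adjusted p = 9.81e-06) and higher in double-positive than in RFP-only cells (3.86 ± 0.30, adjusted p = 7.03e-05). Between double-positive and GFP-only cells the Sox9 difference of -0.31 ± 0.30 did not pass (adjusted p = 0.556), and under quantile normalization it was 0.12.

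**Figure D2:**
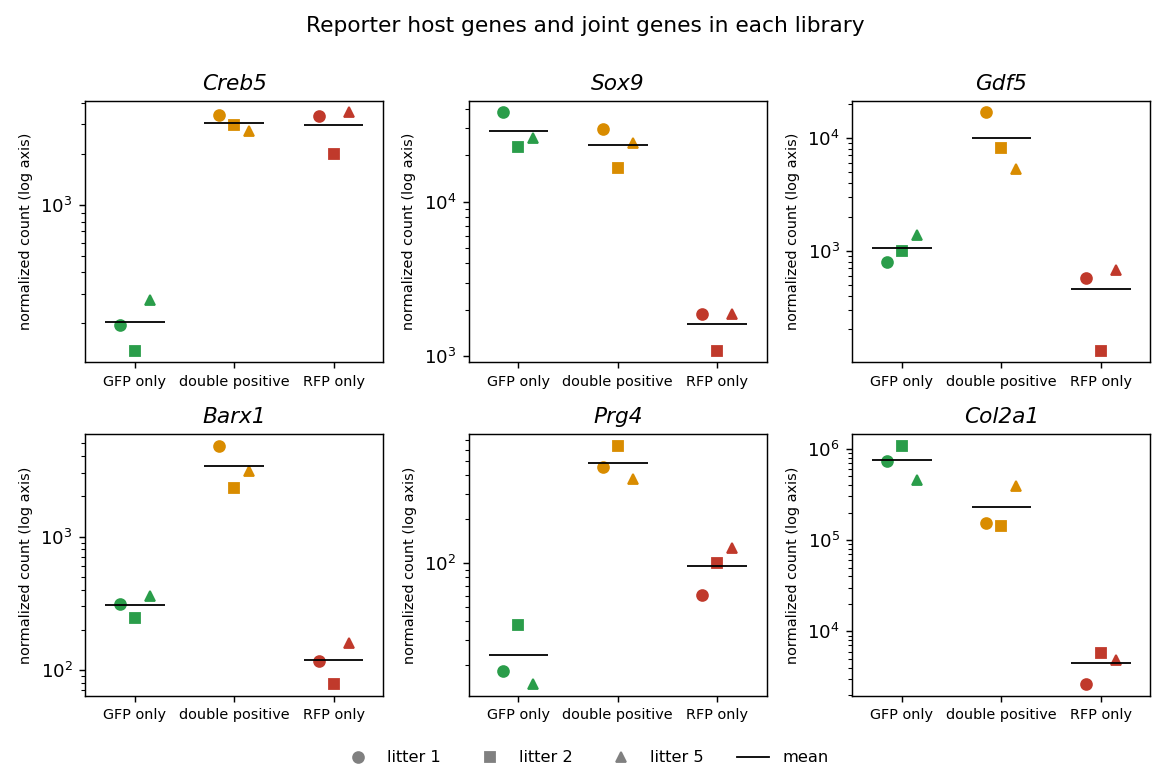
Normalized counts on log axes for Creb5, Sox9, Gdf5, Barx1, Prg4 and Col2a1, 1 point per library, with marker shape for the litter and a line at each population's mean. Creb5 stood between 2006 and 3531 in the 6 libraries with red fluorescence and between 138 and 274 in GFP-only libraries.

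Double-positive cells were compared with GFP-only cells to ask what distinguishes Sox9-reporter cells that also carry the Creb5 reporter. Many genes of the joint interzone were higher in double-positive cells and many genes of maturing cartilage were lower. Gdf5, a BMP-family ligand that marks the interzone, rose from 1058 ± 301 normalized counts in GFP-only cells to 10037 ± 6006 in double-positive cells (log2 fold change 3.11 ± 0.58, adjusted p = 0.00908). Prg4, which encodes the joint lubricant lubricin, rose from 23.7 ± 12.5 to 489 ± 132 (4.39 ± 0.47, adjusted p = 0.000522). Ihh, the hedgehog ligand of prehypertrophic chondrocytes, fell from 13821 ± 2492 to 277 ± 243 (-5.97 ± 0.55, adjusted p = 0.000200). Each of these changes had 1 sign in all 3 litters.

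In total 1472 of 17764 genes differed between double-positive and GFP-only cells (limma, adjusted p under 0.05). Of these 936 were higher and 536 lower in double-positive cells, and 1361 differed by at least 2-fold. The values of the groups did not overlap for 28.1% of tested genes, where chance gives 10%. The count was 855 without the double-positive library of litter 1 and 637 without that of litter 2.

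Of the 34 joint interzone and articular progenitor genes, 16 rose, 2 fell and 16 did not pass, and 23 rose and 3 fell when adjusted over the list alone. Osr2 (4.45 ± 0.35), the secreted Wnt modulator gene Sfrp2 (3.52 ± 0.27) and the homeobox gene Barx1 (3.43 ± 0.35) rose in each litter, while Wnt4 fell (-1.89 ± 0.37). Against all other tested genes the list was higher (camera adjusted p = 8.80e-12, adjusted p = 0.11 with an estimated correlation). Erg, a transcription factor of this list, had 486 ± 47.2 normalized counts in GFP-only and 401 ± 131 in double-positive cells (-0.33 ± 0.39, adjusted p = 0.63). Wnt9a had 326 ± 374 and 394 ± 103 (1.21 ± 0.84, adjusted p = 0.397), and without the GFP-only library of litter 5 its difference was -0.01 (adjusted p = 0.995).

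Of 31 early cartilage matrix and chondrocyte genes, 16 fell and 15 did not pass, while adjusted over the list alone 23 fell and 1 rose (camera adjusted p = 7.89e-14, adjusted p = 0.303 with an estimated correlation). Pcolce2 (-4.05 ± 0.45), Col11a1 (-1.89 ± 0.33) and Col27a1 (-1.43 ± 0.25) were among those that fell. Col2a1, the main collagen of cartilage, went from 755382 ± 311075 to 230109 ± 142626 normalized counts (-1.79 ± 0.45, adjusted p = 0.0321), with log2 ratios within litters 1, 2 and 5 of -2.28, -2.90 and -0.20. The Col2a1 call was lost without the GFP-only or the double-positive library of litter 1 or 2, or the RFP-only library of litter 5, with adjusted p of 0.0518 to 0.129. It was also lost with no filter, quantile normalization, no trend prior, fits of 2 populations or edgeR. Of 19 prehypertrophic, hypertrophic and osteoblast genes, 14 fell and 5 did not pass, and 16 fell when adjusted over the list alone (adjusted p = 4.00e-17, adjusted p = 0.11 with an estimated correlation). Beside Ihh these included the homeobox gene Dlx5 (-3.02 ± 0.26) and Pth1r (-2.49 ± 0.21), the receptor of parathyroid hormone-related protein.

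Some genes of neighboring connective tissues were higher in double-positive than in GFP-only cells. Among 24 tendon and ligament genes 7 rose and 17 did not pass (8 rose adjusted over the list alone; adjusted p = 3.71e-05, adjusted p = 0.454 with an estimated correlation). Thbs4 (3.69 ± 0.30) and Mkx (1.86 ± 0.30) were among them. Among 29 loose connective tissue and perichondrium genes 11 rose, 1 fell and 17 did not pass (16 and 2 adjusted over the list alone; adjusted p = 9.32e-06, adjusted p = 0.454 with an estimated correlation), with Dpp4 (5.91 ± 0.86) and Fap (3.05 ± 0.46) higher and Lum lower (-1.52 ± 0.31). Of 35 limb patterning transcription factors, 10 rose, 1 fell and 24 did not pass (19 and 3 adjusted over the list alone; adjusted p = 2.02e-05, adjusted p = 0.244 with an estimated correlation). Tbx5, a T-box factor best known from the forelimb, rose from 32.5 ± 4.70 to 781 ± 193 (4.53 ± 0.35), Tbx18 rose by 2.61 ± 0.24 and Irx5 fell (-1.73 ± 0.28).

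Markers of other cell types were measured in the same contrast. Of 16 blood and immune cell genes, 10 rose and 6 did not pass, and 15 rose when adjusted over the list alone (median log2 fold change 3.93, camera adjusted p = 7.27e-11, adjusted p = 0.303 with an estimated correlation). Csf1r, the macrophage growth factor receptor gene, had 19.1 ± 15.5 normalized counts in GFP-only and 1277 ± 1110.2 in double-positive cells (6.21 ± 0.93), where its values were 368, 949.6 and 2514 in litters 1, 2 and 5. Of 11 pericyte and smooth muscle genes 4 rose and 7 did not pass (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.000530, adjusted p = 0.278 with an estimated correlation), led by Mcam (2.41 ± 0.25) and Rgs5 (4.77 ± 0.48). Of 15 endothelial genes 2 rose and 13 did not pass by either adjustment (adjusted p = 0.00164, adjusted p = 0.454 with an estimated correlation). The 2 calls, of Esam (adjusted p = 0.0481) and Tek (adjusted p = 0.0452), were both lost without the double-positive library of litter 2 or 5 or any 1 RFP-only library. Over these and the other one-library-out fits that ended them, their adjusted p values were 0.0695 to 0.175 and 0.0678 to 0.17. Among 15 Schwann cell and neuron genes 2 rose, with Nefl at 4.23 ± 0.33, and 4 fell by either adjustment, with Cdh19 at -6.52 ± 0.89 (list not called, adjusted p = 0.485). Of 19 skeletal muscle genes Des rose (2.31 ± 0.40) by either adjustment (for the list, adjusted p = 0.0356, adjusted p = 0.656 with an estimated correlation). That adjusted p was 0.344 and 0.0973 without the GFP-only libraries of litters 1 and 2, and 0.0857 and 0.219 without the double-positive libraries of litters 2 and 5. The muscle list call was also lost with a pseudocount of 5, a filter at a mean of 50, quantile normalization or litter as a random block.

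Signaling genes changed in part between double-positive and GFP-only cells. Of 12 hedgehog pathway genes 4 rose and 8 did not pass (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.00568, adjusted p = 0.454 with an estimated correlation), with the co-receptor genes Gas1 at 4.01 ± 0.26 and Cdon at 2.90 ± 0.25. Without the GFP-only library of litter 5 that adjusted p was 0.0506. Of 20 TGF-beta pathway genes 6 rose and 14 did not pass by either adjustment, led by Inhba (2.36 ± 0.27) and Inhbb (2.96 ± 0.46). The adjusted p of that list, 0.0181, was 0.0577 with litter as a block and 0.0932 without the double-positive library of litter 5 (adjusted p = 0.454 with an estimated correlation). Of 18 FGF pathway genes 3 rose and 15 did not pass (6 rose adjusted over the list alone), with Spry1 at 1.63 ± 0.32. The FGF list's adjusted p = 0.0053, adjusted p = 0.454 with an estimated correlation, was 0.0565 without the double-positive library of litter 5. BMP and GDF pathway genes (4 higher and 3 lower of 28, or 4 and 4 adjusted over the list alone) included Grem1 (2.92 ± 0.36) and Bmp7 (-1.80 ± 0.23), and the list was not called (adjusted p = 0.88). Wnt pathway genes (5 higher and 4 lower of 35, or 7 and 9 adjusted over the list alone) included Ror1 (2.48 ± 0.40) and Notum (-3.82 ± 0.37), and the list was not called (adjusted p = 0.607).

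Nxph1, Rpl35a-ps3, Ptpro, C3ar1 and Ano5 had the largest rises in double-positive against GFP-only cells among genes that met the naming rule. Nxph1 (a neurexophilin), Rpl35a-ps3 and Ptpro (a receptor tyrosine phosphatase) had no read in GFP-only libraries and were at least 816-fold, 173-fold and 161-fold higher, against a floor of 3 reads over the group. Rpl35a-ps3 is a pseudogene that can share reads with its parent, so its value is uncertain, and its call was lost without the double-positive library of litter 1 or 2 (adjusted p of 0.0559 to 0.075). Ano5, with 2 reads in the GFP-only libraries, stood at a ratio of 331 (95% counting interval 91.3 to 2730). C3ar1, a complement receptor gene of myeloid cells, changed by 7.21 ± 1.08. The largest falls were those of Ostn (-6.78 ± 0.75), Cdh19 (-6.52 ± 0.89), Apof (-6.32), Smim5 (-6.03 ± 0.62) and Ihh (-5.97 ± 0.55).

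RFP-only and GFP-only cells were compared as the populations with either reporter alone. Cartilage genes were higher in GFP-only cells, and many genes of connective tissue, tendon and muscle were higher in RFP-only cells. Col2a1 had 755382 ± 311075 normalized counts in GFP-only and 4449 ± 1639 in RFP-only cells (log2 fold change -7.40 ± 0.45, adjusted p = 4.96e-06). Thbs4, a matrix gene of tendon, rose from 240.4 ± 83.3 to 8059 ± 556 (5.11 ± 0.30, adjusted p = 4.96e-06). Des, which encodes the muscle filament desmin, rose from 61.6 ± 15.4 to 2147 ± 904 (5.02 ± 0.40, adjusted p = 1.59e-05). These signs held in all 3 litters.

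In this comparison 3601 of 17764 genes differed, 2094 higher and 1507 lower in RFP-only cells, and 3128 by at least 2-fold. The groups did not overlap for 39.4% of tested genes, against 10% by chance. The count was 2258 without the RFP-only library of litter 1 and 2190 without that of litter 5.

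Of the 31 early cartilage matrix and chondrocyte genes, 30 fell and 1 did not pass in RFP-only against GFP-only cells, and 31 fell when adjusted over the list alone (median -7.37, camera adjusted p = 3.72e-41, adjusted p = 0.144 with an estimated correlation). Col9a1 (-7.90 ± 0.45), Matn4 (-6.49 ± 0.31) and Wwp2 (-4.72 ± 0.26) were among them. Of 19 prehypertrophic, hypertrophic and osteoblast genes, 16 fell and 3 did not pass by either adjustment (adjusted p = 3.45e-15, adjusted p = 0.144 with an estimated correlation), with Ihh at -9.07 ± 0.55 and Dlx5 at -4.63 ± 0.26. Of 23 tested identifiers of glycolysis and hypoxia genes, among which Aldoa has a pair of gene identifiers, 16 fell and 7 did not pass (16 fell and 1 rose adjusted over the list alone; adjusted p = 3.55e-08, adjusted p = 0.277 with an estimated correlation). The glucose transporter gene Slc2a1 (-2.69 ± 0.33) and the carbonic anhydrase gene Car9 (-3.86 ± 0.50) were among these.

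Interzone genes went both ways in this contrast, with 18 higher, 6 lower and 10 not passing of 34 (18 and 7 adjusted over the list alone; camera adjusted p = 0.0031, adjusted p = 0.388 with an estimated correlation). Osr1 (4.91 ± 0.37), Osr2 (4.13 ± 0.35) and Lgr5 (3.89 ± 0.38) were higher in RFP-only cells. Nog, a BMP antagonist gene (-3.15 ± 0.42), and Erg (-1.96 ± 0.39, adjusted p = 0.00503) were lower. Gdf5 had 456 ± 286 normalized counts in RFP-only cells and did not pass (-1.48 ± 0.58, adjusted p = 0.0958). Prg4 was higher in RFP-only cells at 96.0 ± 33.4 (2.02 ± 0.47, adjusted p = 0.0118, and 0.058 without the RFP-only library of litter 5). Wnt9a was higher at 1141 ± 104 (2.77 ± 0.84, adjusted p = 0.0393), a call lost without the GFP-only library of litter 1 or any 1 of the double-positive and RFP-only libraries, with adjusted p of 0.0554 to 0.108, and at 0.0854 in a fit of these 2 populations alone.

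Of 29 loose connective tissue and perichondrium genes, 24 rose and 5 did not pass by either adjustment (adjusted p = 9.01e-13, adjusted p = 0.277 with an estimated correlation), led by Meox2 (2.34 ± 0.22), Ebf2 (4.80 ± 0.60) and Dpp4 (6.71 ± 0.86). Of 24 tendon and ligament genes 11 rose, 1 fell and 12 did not pass (12 and 1 adjusted over the list alone; adjusted p = 8.83e-06, adjusted p = 0.343 with an estimated correlation), with Kera at 5.03 ± 0.55 and Fibin at -1.41 ± 0.23. Limb patterning transcription factors had 15 higher, 1 lower and 19 not passing of 35 (18 and 3 adjusted over the list alone; adjusted p = 1.51e-05, adjusted p = 0.237 with an estimated correlation), with Meis1 at 2.25 ± 0.29 and Msx1 at -2.89 ± 0.52. FGF pathway genes had 9 higher, 1 lower and 8 not passing of 18 (9 and 2 adjusted over the list alone; adjusted p = 0.00498, adjusted p = 0.434 with an estimated correlation), with Fgf10 at 4.38 ± 0.58 and Fgfr2 at -2.27 ± 0.33.

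Many markers of several other cell types were higher in RFP-only than in GFP-only cells. Of 19 skeletal muscle genes 15 rose and 4 did not pass (16 rose and 1 fell adjusted over the list alone; median 4.35, adjusted p = 4.58e-09, adjusted p = 0.325 with an estimated correlation). Cdh15 (5.03 ± 0.54) and Tnnt1 (4.16 ± 0.51) rose with Des, and the list's median log2 values in the RFP-only libraries were 7.99, 9.27 and 9.04 for litters 1, 2 and 5. Of 11 pericyte and smooth muscle genes 9 rose and 2 fell by either adjustment (adjusted p = 0.0016, adjusted p = 0.277 with an estimated correlation), with Acta2 at 4.06 ± 0.53 and Cspg4 at -3.61 ± 0.33. Of 15 endothelial genes 8 rose, 1 fell and 6 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.00105, adjusted p = 0.434 with an estimated correlation), with Tek at 4.91 ± 0.78. The gene that fell was Erg, which also belongs to the interzone list. Of 16 blood and immune cell genes 7 rose and 9 did not pass (10 rose adjusted over the list alone; adjusted p = 0.000425, adjusted p = 0.488 with an estimated correlation), with Csf1r at 5.03 ± 0.93. Of 11 erythroid genes the embryonic globin genes Hba-x (4.18 ± 0.48) and Hbb-y (4.16 ± 0.48) rose by either adjustment (for the list, adjusted p = 0.0191, adjusted p = 0.434 with an estimated correlation). That adjusted p was 0.0953 without the GFP-only library of litter 1 and 0.0665 without the RFP-only library of litter 2.

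Other lists had members on both sides and were not called between RFP-only and GFP-only cells. Schwann cell and neuron genes had 6 higher and 3 lower of 15 (7 and 6 adjusted over the list alone; adjusted p = 0.328), with Nefl at 5.12 ± 0.33 and S100b at -5.48 ± 0.61. Epidermis genes had 1 higher and 2 lower of 14 by either adjustment, with Perp at -2.47 ± 0.44 (for the list, adjusted p = 0.0834, and 0.0455 with litter as a block). The epidermis p was 0.0462 without the GFP-only library of litter 1 and 0.0249 without the RFP-only library of litter 2. BMP and GDF pathway genes had 7 higher and 7 lower of 28 (9 and 8 adjusted over the list alone; adjusted p = 0.692), with Chrd at 3.12 ± 0.48 and Bmp5 at -2.26 ± 0.33. Wnt pathway genes had 12 and 8 of 35 (13 and 8 adjusted over the list alone; adjusted p = 0.268), with Wnt2 at 4.56 ± 0.58 and the receptor gene Fzd9 at -5.76 ± 0.38. Retinoic acid pathway genes had 6 and 4 of 16 (9 and 4 adjusted over the list alone; adjusted p = 0.0795), with the retinoic acid-producing enzyme gene Aldh1a2 at 3.81 ± 0.57 and Dhrs3 at -2.15 ± 0.33. CREB and ATF family genes and cofactors had 4 and 1 of 20 (6 and 2 adjusted over the list alone; adjusted p = 0.122), with Crem at 1.71 ± 0.26 and Sik1 at 2.49 ± 0.52.

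Gbp6, Mchr1 (7.70 ± 0.79), Nxph1, Mybpc1 (7.52 ± 0.97) and Cilp (7.27 ± 0.88) had the largest rises in RFP-only against GFP-only cells under the naming rule. Gbp6 and Nxph1 had no read in GFP-only libraries and were at least 283-fold and 174-fold higher. The largest falls were those of Snorc (-9.93 ± 0.85), Itih5l-ps (-9.87 ± 0.64, named as a pseudogene and so uncertain), the forkhead gene Foxa3 (-9.65 ± 0.75), Matn1 (-9.29 ± 0.67) and Chad (-9.21 ± 0.72).

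Double-positive cells were then compared with RFP-only cells to ask what distinguishes Creb5-reporter cells that also carry the Sox9 reporter. Cartilage matrix genes were higher in double-positive cells, as were some interzone genes, and some muscle genes were lower. Col2a1 was higher by 5.60 ± 0.45 on the log2 scale (adjusted p = 8.32e-05) and Gdf5 by 4.60 ± 0.58 (adjusted p = 0.00159), each in all 3 litters. Des went from 2147 ± 904 normalized counts in RFP-only cells to 314 ± 93.7 in double-positive cells (-2.71 ± 0.40, adjusted p = 0.00432).

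Between these populations 506 of 17764 genes differed, 319 higher and 187 lower in double-positive cells, and 500 by at least 2-fold. The groups did not overlap for 23.8% of tested genes, where chance gives 10%. The count was 1050 without the GFP-only library of litter 5, 217 and 223 without the double-positive libraries of litters 1 and 5, and 277, 226 and 236 without the RFP-only libraries of litters 1, 2 and 5. Fits of 2 populations alone gave 1008 genes here and 697 for double-positive against GFP-only cells. Which of these comparisons has more called genes therefore depends on the shared estimate of the spread.

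All 31 early cartilage matrix and chondrocyte genes were higher in double-positive than in RFP-only cells by either adjustment (median 5.56, camera adjusted p = 1.37e-73, adjusted p = 0.048 with an estimated correlation). Matn4 (5.89 ± 0.31), Wwp2 (4.21 ± 0.26) and Sox5 (4.63 ± 0.31), a transcription factor that acts with Sox9, were among them. Of 19 prehypertrophic, hypertrophic and osteoblast genes 4 rose and 15 did not pass (7 rose and 2 fell adjusted over the list alone; adjusted p = 3.01e-05, adjusted p = 0.342 with an estimated correlation), with Dlx5 at 1.61 ± 0.26. Of 23 glycolysis and hypoxia identifiers 4 rose and 19 did not pass (11 rose adjusted over the list alone; adjusted p = 1.59e-10, adjusted p = 0.256 with an estimated correlation), with Car9 at 4.48 ± 0.50.

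Of 34 interzone genes 6 rose and 28 did not pass (11 rose and 1 fell adjusted over the list alone; adjusted p = 0.000398, adjusted p = 0.342 with an estimated correlation). Barx1 (4.83 ± 0.35), Gdf5 and Pthlh (2.34 ± 0.30), which encodes parathyroid hormone-related protein, were among those that rose. Prg4 was higher by 2.37 ± 0.47 (adjusted p = 0.0236), a call lost without any 1 of the 6 double-positive and RFP-only libraries (adjusted p of 0.0508 to 0.0988). Erg did not pass at 1.63 ± 0.39 (adjusted p = 0.052), but passed without the GFP-only library of litter 5, the double-positive library of litter 2 or the RFP-only library of litter 2 (adjusted p of 0.0342 to 0.0383). With every library kept, Erg also passed with a pseudocount of 5, a filter at a mean of 50, quantile normalization, litter as a random block, array weights, DESeq2 or the length trend removed. Wnt9a did not pass (-1.56 ± 0.84, adjusted p = 0.508), but passed in a fit of these 2 populations alone (adjusted p = 0.00976).

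Of 19 skeletal muscle genes 9 fell and 10 did not pass in double-positive against RFP-only cells (14 fell adjusted over the list alone; adjusted p = 4.53e-16, adjusted p = 0.256 with an estimated correlation), with Cdh15 at -3.59 ± 0.54 and Tnnt1 at -3.29 ± 0.51. Of 29 loose connective tissue and perichondrium genes 4 fell and 25 did not pass (13 fell adjusted over the list alone; adjusted p = 1.99e-11, adjusted p = 0.313 with an estimated correlation). Of 24 tendon and ligament genes 2 fell, 1 rose and 21 did not pass (3 and 1 adjusted over the list alone; adjusted p = 0.0236, adjusted p = 0.648 with an estimated correlation). The tendon p was 0.187 without the double-positive library of litter 1 and 0.152 without the RFP-only library of litter 5, and the call was lost with array weights or no trend prior. Hba-x (-3.09 ± 0.48) and Hbb-y (-3.06 ± 0.48) fell by either adjustment among 11 erythroid genes (for the list, adjusted p = 0.00367, adjusted p = 0.354 with an estimated correlation). Of 15 Schwann cell and neuron genes 3 fell, 2 rose and 10 did not pass (6 and 2 adjusted over the list alone; adjusted p = 0.00312, adjusted p = 0.256 with an estimated correlation). The 16 blood and immune cell genes were higher as a list (median 1.40, adjusted p = 9.44e-05, adjusted p = 0.518 with an estimated correlation), and so were the 14 epidermis genes (median 0.85, adjusted p = 0.0451, adjusted p = 0.518 with an estimated correlation), while no gene of either list passed by either adjustment. The blood list call was lost when all libraries of litter 5 were left out. The epidermis p was 0.0736, 0.142 and 0.204 without the GFP-only, double-positive or RFP-only library of litter 5. That call was also lost with a filter at a mean of 50, quantile normalization, litter as a random block, array weights, no trend prior, fits of 2 populations, DESeq2 or the length trend removed.

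Wnt pathway genes had 6 lower, 3 higher and 26 not passing of 35 (14 and 4 adjusted over the list alone; adjusted p = 0.00661, adjusted p = 0.354 with an estimated correlation), with Fzd9 higher by 4.63 ± 0.38. Limb patterning transcription factors had 2 higher and 2 lower of 35 (4 and 4 adjusted over the list alone), and the list was not called (median -0.22, adjusted p = 0.371). Of 28 BMP and GDF pathway genes Bmp5 (2.06 ± 0.33) and Gdf10 (1.88 ± 0.27) rose by either adjustment, and the list was not called (adjusted p = 0.615). Retinoic acid pathway genes had 4 higher and 1 lower of 16 (4 and 9 adjusted over the list alone; adjusted p = 0.129, and 0.0471 without the double-positive library of litter 2). Cyp26a1, which encodes an enzyme that degrades retinoic acid, was higher by 4.69 ± 0.59 at 1383 ± 457 against 62.8 ± 41.2 normalized counts.

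Cytl1 (7.43 ± 0.55), Foxa3 (7.27 ± 0.75), Itih5l-ps (7.18 ± 0.64, uncertain as above), Serpina3n (6.97 ± 0.93) and Matn1 (6.87 ± 0.67) had the largest rises in double-positive against RFP-only cells under the naming rule. Gad2, a glutamate decarboxylase gene, had 2 reads in the double-positive libraries and was higher in RFP-only cells by a ratio of 230.0 (95% counting interval 63.1 to 1900). Chrng (-5.65 ± 1.17), Trim55 (-5.62 ± 1.19, adjusted p = 0.0314, and 0.057 with litter as a block), Xdh (-5.46 ± 1.01) and Cdh7 (-5.45 ± 0.91) were also lower. The Chrng call was lost without the double-positive library of litter 1 or 2 or the RFP-only library of litter 2 or 5 (adjusted p of 0.0669 to 0.131), and that of Trim55 without the double-positive library of litter 1 or 2 or any 1 RFP-only library (0.0604 to 0.156). The Xdh call was lost without the double-positive library of litter 1 or 5 or any 1 RFP-only library (0.05 to 0.0794), and that of Cdh7 without the RFP-only library of litter 1 or 2 (0.0513 to 0.0879).

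**Figure D3:**
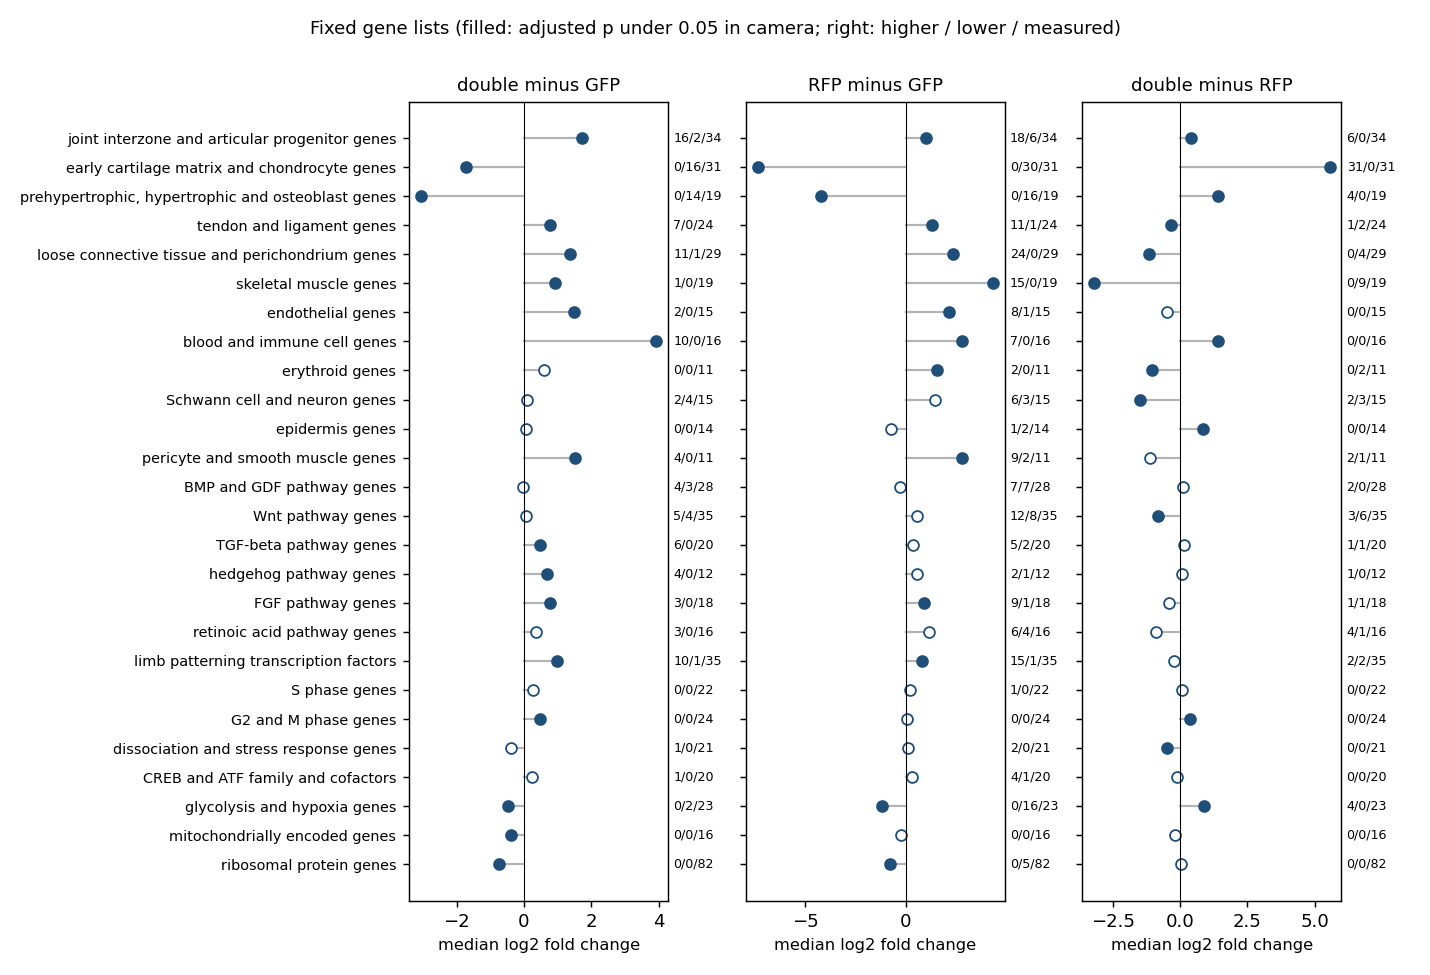
Median log2 fold change of each fixed gene list in the 3 comparisons (x axes, which differ in range), 1 row per list, with filled points for lists called by camera with a preset correlation and, at the right, the genes higher, lower and measured. The cartilage list stood at -1.73, -7.37 and 5.56, the interzone list at 1.72, 1.01 and 0.41 and the muscle list at 0.93, 4.35 and -3.20 for double-positive against GFP-only, RFP-only against GFP-only and double-positive against RFP-only cells.

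Genes higher in double-positive cells than in both single-positive populations numbered 42 of 17764, with Gdf5, Barx1, Prg4, Pthlh and Dkk3 of the interzone list among them. Barx1 (ENSMUSG00000021381, plus strand of chromosome 13, 48662998 to 48666507, GRCm38) had 304 ± 56.2, 3411 ± 1263 and 118 ± 40.8 normalized counts in GFP-only, double-positive and RFP-only cells. Gdf5 (ENSMUSG00000038259, minus strand of chromosome 2, 155941023 to 155945367) had 1058 ± 301, 10037 ± 6006 and 456 ± 286. Prg4 (ENSMUSG00000006014, minus strand of chromosome 1, 150449412 to 150466165) had 23.7 ± 12.5, 489 ± 132 and 96.0 ± 33.4. The 5 interzone genes compare with 0.0804 expected of 34 (Fisher's exact test, which treats genes as independent, adjusted p = 3.97e-07 over 26 lists). Of these, Prg4 loses its call against RFP-only cells without any 1 of the 6 double-positive and RFP-only libraries. Gdf5 and Barx1 keep both calls in every one-library-out fit. With the whole of litter 1 left out, however, these genes do not both keep them. The 2 limb patterning factors among the 42, Hoxd9 and Tbx5, compare with 0.0828 expected of 35 (adjusted p = 0.0402). That excess rests on 2 calls that are lost when single libraries are left out.

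Under the naming rule the genes highest relative to both populations were Krt17, Barx1, Cer1, Ano5, Pax9, Gdf5, Fbp2 and Cyp26a1. The keratin gene Krt17 was higher by 3.90 ± 0.47 against GFP-only and 3.95 ± 0.47 against RFP-only cells. Pax9, a paired-box transcription factor gene, was higher by 4.85 ± 0.58 and 3.13 ± 0.58, a call against RFP-only cells lost without the double-positive library of litter 1 or 5 or the RFP-only library of litter 2 or 5 (adjusted p of 0.05 to 0.0882). Cer1, which encodes a secreted antagonist of BMP and Nodal ligands, was higher by 3.80 ± 0.71 and 3.32 ± 0.71. Against RFP-only cells its adjusted p was 0.0332, or 0.0506 with litter as a block, and 0.0663 to 0.155 without the double-positive library of litter 1 or 2 or any 1 RFP-only library. Fbp2 was higher by 2.81 ± 0.59 (adjusted p = 0.0734 without the double-positive library of litter 1) and 4.88 ± 0.59. Cyp26a1 was higher by 2.45 ± 0.59 and 4.69 ± 0.59, the first of these calls being lost without the GFP-only library of litter 1 or 2 or the double-positive library of litter 2 or 5 (adjusted p of 0.0511 to 0.103). Against RFP-only cells the calls of Ano5 (3.14 ± 0.74), Hoxd9 (1.64 ± 0.38) and Tbx5 (adjusted p = 0.0457) were lost without any 1 of the 6 double-positive and RFP-only libraries, and that of Tbx5 also without the GFP-only library of litter 1. Their adjusted p values were then 0.0747 to 0.212, 0.0697 to 0.195 and 0.0517 to 0.216, and that of Tbx5 was 0.0511 with litter as a block.

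Genes lower in double-positive cells than in both other populations numbered 11. The lowest under the naming rule were Cpa6 (-2.90 ± 0.38 against GFP-only and -2.31 ± 0.38 against RFP-only cells), the secreted Wnt antagonist gene Dkk1 (-1.89 ± 0.43 and -1.95 ± 0.43), Lmo3 (-1.89 ± 0.42 and -1.88 ± 0.42), Irx5 (-1.73 ± 0.28 and -2.03 ± 0.28) and the lumican gene Lum (-1.52 ± 0.31 and -1.51 ± 0.31). The Dkk1 call against GFP-only cells was lost without the GFP-only library of litter 2 or the double-positive library of litter 1 or 2 (adjusted p of 0.0516 to 0.0808), and against RFP-only cells without the double-positive library of litter 1 or 2 or the RFP-only library of litter 2 or 5 (0.0849 to 0.167). The Lmo3 call against GFP-only cells was lost without the double-positive library of litter 1 or 5 (0.0662 to 0.0728). Against RFP-only cells it was lost without the GFP-only library of litter 1 or 2, the double-positive library of litter 1 or 5 or any 1 RFP-only library (0.0501 to 0.165), and with litter as a block (0.0541). The Lum call against RFP-only cells was lost without the double-positive library of litter 1 or 5 or any 1 RFP-only library (0.073 to 0.133).

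Independent lists of these sizes would share 16.8 genes higher and 5.64 genes lower. Part of the excess may come from the double-positive libraries that both comparisons share, which are too few to divide. The count of 42 was 71 without the GFP-only library of litter 5. It was 8, 14 and 14 without the double-positive libraries of litters 1, 2 and 5, and 14, 14 and 20 without the RFP-only libraries of litters 1, 2 and 5. The count of 11 was 29 without the GFP-only library of litter 5. It was 7 and 7 without the double-positive libraries of litters 1 and 5, and 5, 2 and 4 without the RFP-only libraries of litters 1, 2 and 5.

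**Figure D4:**
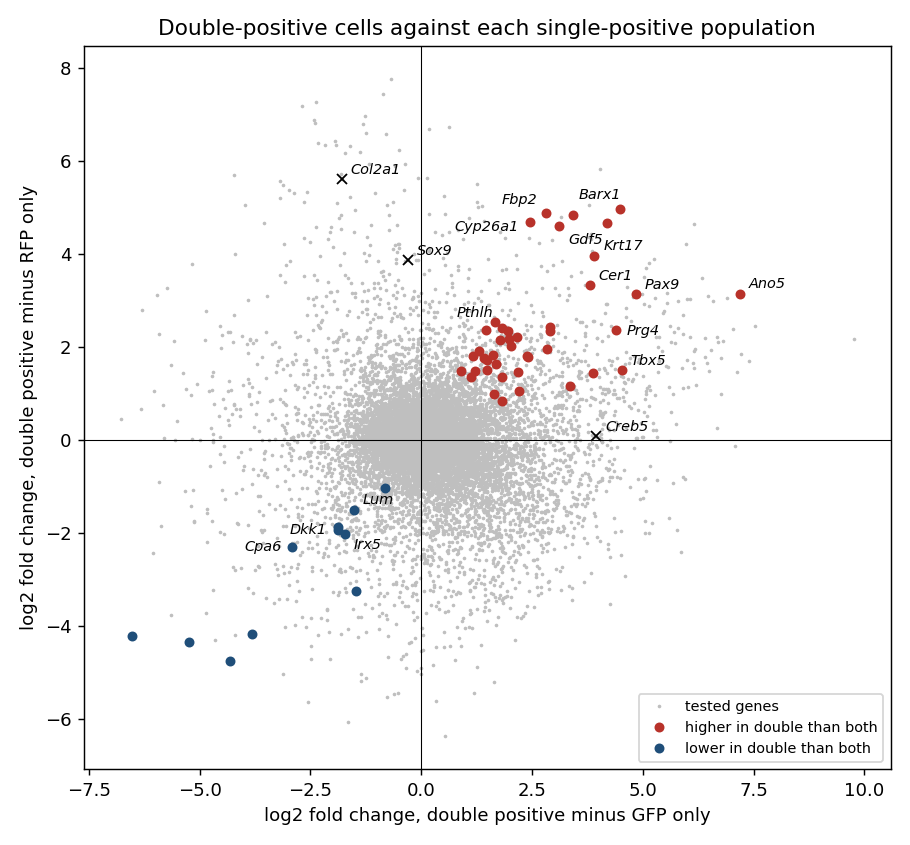
Log2 fold change of double-positive against GFP-only cells (x axis) and against RFP-only cells (y axis), 1 point per tested gene, with red for the 42 genes higher and blue for the 11 genes lower than in both populations. Barx1 lies at 3.43 and 4.83, Gdf5 at 3.11 and 4.60, and the host genes Creb5 and Sox9 at 3.95 and 0.08 and at -0.31 and 3.86.

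Most genes that separated the single-positive populations had intermediate levels in double-positive cells. On a scale from 0 at the GFP-only mean to 1 at the RFP-only mean of log2 values, the 1920 genes at least 2-fold higher in RFP-only cells had a median position of 0.642, and 82.8% of them lay between both populations. The 1208 genes at least 2-fold higher in GFP-only cells had a median position of 0.569, and 87.6% lay between. The quartiles of the positions were 0.446 and 0.839 for the first set and 0.323 and 0.798 for the second. Both sets were chosen for the difference between these ends in the same libraries, which favors positions between, and no reference share was computed. Thbs4, for example, had 240.4 ± 83.3, 3137 ± 1114 and 8059 ± 556 normalized counts in GFP-only, double-positive and RFP-only cells.

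Genes of general cell processes were measured in the same contrasts. The 82 ribosomal protein genes had medians of -0.76 in double-positive and -0.79 in RFP-only against GFP-only cells (camera adjusted p = 2.82e-15, adjusted p = 0.454 with an estimated correlation, and 3.08e-12, adjusted p = 0.508 with an estimated correlation). Of them 5 fell in RFP-only cells and 77 did not pass, while 0 fell by limma when adjusted over the list alone. The Rpl5 and Rpl36al calls were lost with litter as a block (adjusted p = 0.0524 and 0.0543). The list's median log2 value was 14.53 in the GFP-only library of litter 5 and between 12.58 and 13.10 in the other 8 libraries. The 24 genes of G2 and M phase had medians of 0.47 and 0.35 in double-positive against GFP-only and RFP-only cells (adjusted p = 0.000203, adjusted p = 0.454 with an estimated correlation, and 3.01e-05, adjusted p = 0.354 with an estimated correlation), and none of them passed but for 3 that rose against GFP-only cells when adjusted over the list alone. The 22 S phase genes had a median of 0.27 against GFP-only cells (adjusted p = 0.088, but 0.038 without the GFP-only library of litter 1 and 0.00853 without the double-positive library of litter 2), and passed with no filter, quantile normalization or array weights. The 16 mitochondrially encoded genes had a median of -0.38 in double-positive against GFP-only cells (adjusted p = 0.0207, adjusted p = 0.656 with an estimated correlation). The mitochondrial p was 0.253, 0.0755 and 0.175 without the GFP-only library of litter 5 and the double-positive libraries of litters 1 and 5, and the direction turned under quantile normalization. The mitochondrial call was also lost with no filter, litter as a random block, array weights, DESeq2 or the length trend removed. The 21 dissociation and stress response genes were not called against GFP-only cells (adjusted p = 0.479 for double-positive and 0.414 for RFP-only cells). The first of these was 0.0475 without the GFP-only library of litter 2 and 0.0047 without the double-positive library of litter 5. Against RFP-only cells the stress list was lower in double-positive cells (median -0.50, adjusted p = 0.0194, adjusted p = 0.678 with an estimated correlation), with none of its genes passing by either adjustment. That adjusted p was 0.126 and 0.526 without the double-positive libraries of litters 1 and 2 and 0.152 without the RFP-only library of litter 5, and the call was lost with edgeR and DESeq2. Of 23 glycolysis and hypoxia identifiers 2 fell in double-positive against GFP-only cells and 21 did not pass (6 fell adjusted over the list alone; adjusted p = 0.0053, adjusted p = 0.459 with an estimated correlation, and 0.0597 without the double-positive library of litter 2), a list call also lost under quantile normalization.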

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

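Tests with the length trend removed were chosen only after the data were seen. Creb5 and Sox9 kept direction and call in their 4 called contrasts in each one-library-out fit, with log2 fold changes of 3.70 to 4.20, 3.63 to 4.13, -4.32 to -3.90 and 3.60 to 4.09. Of 241 called pairs of named gene and comparison, 174 kept the call in every one-library-out fit and 67 lost it in at least 1. Under settings that keep every library, 3561 of 3658 named gene results and 1128 of 1170 list results kept direction and side. The replicate block (litter) gave 1616, 3673 and 558 genes for double-positive against GFP-only, RFP-only against GFP-only and double-positive against RFP-only cells, with 37 higher and 13 lower than both. It ended 10 calls of named genes (Fgf2, Rarb, Epcam, Rpl36al, Rpl5, Trim55, Pfkl, Tbx5, Cer1 and Lmo3) and that of the TGF-beta list in double-positive against GFP-only cells, added the epidermis list in RFP-only against GFP-only cells, and changed no other call of a named gene or list. Quantile normalization shifted the log2 fold changes of all genes by a median of -0.15 and -0.17 in both contrasts against GFP-only cells. It changed the call or direction of 11 of 78 list results. Muscle and glycolysis in double-positive against GFP-only and epidermis in double-positive against RFP-only cells lost their calls, mitochondrial genes turned, S phase was added in double-positive against GFP-only cells, and epidermis, TGF-beta, retinoic acid, S phase, G2 and M phase and stress lists were added in RFP-only against GFP-only cells.

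Leaving out 1 library gave 1938 to 3328 genes differing among the populations, 637 to 1553 for double-positive against GFP-only, 2190 to 3716 for RFP-only against GFP-only and 217 to 1050 for double-positive against RFP-only cells, and 8 to 71 higher and 2 to 29 lower than both; fewer libraries entered these fits. Without litter 1 the same 6 counts were 1072, 335, 1598, 112, 1 and 2, and without litter 2 they were 1172, 229, 1811, 131, 4 and 0 (limma). Without litter 5 double-positive against RFP-only cells gave 263 and 26 were higher than both. Array weights, in which the GFP-only library of litter 5 had a weight of 0.139, gave 4653 genes among the populations, 1545 for double-positive against RFP-only cells, 107 higher and 54 lower than both. Fits of 2 populations gave 697 for double-positive against GFP-only and 1008 for double-positive against RFP-only cells. DESeq2 gave 2780 and 1152 for these, with 113 higher and 56 lower than both, and edgeR gave 5365 among the populations. Genes lower than both numbered 7 with no filter, 7 without the trend prior, 20 under quantile normalization and 22 with the replicate block and the length trend removed. Camera with an estimated correlation called 0 lists for double-positive against GFP-only, 0 for RFP-only against GFP-only and 1 for double-positive against RFP-only cells, and fry called 10 for the first and 5 for the last. Directions turned for Sox9 in double-positive against GFP-only cells under quantile normalization (0.12), for Wnt9a there without the GFP-only library of litter 5 (-0.0093, of a one-library-out range up to 2.29), for Creb5 in double-positive against RFP-only cells without the double-positive library of litter 1 (-0.01), the RFP-only library of litter 2 (-0.18) or litter 2 (-0.17) (one-library-out range up to 0.23), and for the mitochondrial list in double-positive against GFP-only cells under quantile normalization (adjusted p = 0.981). Leaving out the GFP-only library of litter 5 does not change the means of double-positive and RFP-only cells. The rise from 506 to 1050 genes between them thus came from the shared estimate of the spread. For the other changes the cause was not tested beyond the fewer libraries.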

Other observations

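The tests of a mixture, of blood cells, of read number, of transcript length, of a stress response and of the muscle genes below were chosen only after the data were seen, while those of other splits were set before their counts were seen.

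The hindlimb factor genes Tbx4 and Pitx1, picked after their values were seen, had their highest means in double-positive cells, while the fixed list of limb patterning factors was not called against RFP-only cells (median -0.22, adjusted p = 0.371). Tbx4, a T-box factor gene, had 1541 ± 724 normalized counts in GFP-only, 5303 ± 998 in double-positive and 2314 ± 500.3 in RFP-only cells, and Pitx1, which acts upstream of it in the hindlimb, had 4703 ± 1528, 13942 ± 3467 and 9936 ± 2154. Genes of retinoic acid handling had their highest means in different populations. Aldh1a2, which produces the ligand, had 172 ± 154, 509 ± 317 and 1937 ± 507, and the degrading enzyme gene Cyp26a1 had 260.5 ± 118, 1383 ± 457 and 62.8 ± 41.2. Col10a1, a collagen gene of hypertrophic cartilage, varied within GFP-only cells, with 10049, 72495 and 58216 in litters 1, 2 and 5.

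Other splits of the libraries bear on chance. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For double-positive against GFP-only, RFP-only against GFP-only and double-positive against RFP-only cells the real counts of 1472, 3601 and 506 genes were matched by 1, 1 and 1 of 10 splits, the real one included, and the highest others were 0, 1 and 1 (limma). For the gene lists 1, 2 and 4 of 10 splits reached the real 17, 14 and 14, with highest others of 14, 14 and 16, so list calls at the preset correlation also arise in other splits. For the F-test 1 of 100 drawn splits, the real one, gave as many as 3050 genes, with a highest other of 1217. This makes chance an unlikely source but cannot exclude it, since the splits were drawn without regard to litter. For genes higher and lower than both, 2 and 2 of 100 gave as many as 42 and 11. In each case the other split was the real groups with GFP-only libraries in the place of the double-positive ones (434 and 750), and the other 98 of these 100 gave at most 0 and 1 by limma. Among the 100 splits drawn for the F-test, 3 others gave 48 to 286 higher and 154 to 523 lower, each with all GFP-only or all RFP-only libraries in the place of the double-positive ones, so such counts also arise where 1 real population is set against mixed groups.

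The 42 genes higher in double-positive cells than in both other populations might arise if that gate held a mixture of both. A mixture gives values between its parts, so genes chosen in 2 litters should exceed both in the third in at most 50% of cases. Of 50 such genes, 28, 46 and 47 exceeded both single-positive libraries in held-out litters 1, 2 and 5, or 56% (95% interval 41.3 to 70), 92% (80.8 to 97.8) and 94% (83.5 to 98.7), where 29.3%, 28.6% and 24.1% of all genes did. The intervals treat genes as independent, though genes can vary together, and each litter has 1 library per population. In litters 2 and 5 the shares argue against a mixture of both populations as sorted, but not against a mixture of selected cells of each. In litter 1 the interval lies above the share of all genes but includes 50%, so there a mixture cannot be told apart from expression of these cells. Of the 42, 19% (8, 95% interval 8.6 to 34.1) had their highest double-positive value in litter 5, where 100% of 16 blood list genes did. That interval, too, treats genes as independent and rests on few libraries. The calls that define the 42 favor genes that vary little among the double-positive libraries. There the blood list had median log2 values of 7.84, 9.14 and 10.26 in litters 1, 2 and 5. Genes that follow blood content were thus less likely to be among the 42. The share therefore cannot decide whether blood and immune cells in the gate are a source of them. The blood list itself was higher in double-positive than in RFP-only cells (median 1.40, adjusted p = 9.44e-05, adjusted p = 0.518 with an estimated correlation), a call lost without litter 5. By limma 0 of its genes were among the 42. Such cells may be in the gate, and their part in the 42 stays open. Regulation by Creb5 with Sox9 stays open as an untested hypothesis.

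The GFP-only library of litter 5 lay apart from the other GFP-only libraries (SD of log2 differences 1.43 and 1.48, against 1.11 between those). Fewer reads are argued against, since its 36.5 (in units of 1e6 reads) lay between those of the others. Its deviation from the other GFP-only libraries had a Spearman correlation with transcript length of -0.36. Length here is that of all annotated exons of a gene joined, not of the transcripts expressed. The values for litters 1 and 2, whose references include this library, were 0.30 and 0.23. In the double-positive and RFP-only libraries the same correlation lay between -0.24 and 0.23, the ends being RFP-only litters 2 and 5. With a length trend removed the ratio of distances was 1.25, against 1.31 before. Whether transcript length is a cause cannot be told apart from a difference of the sample, because the correction removes part of any real change. The stress list was higher there by a median of 0.92 with the length trend removed (0.82 uncorrected). The corrected value lay at percentile 100 of 10000 matched lists. Those lists drew genes independently, while the estimated correlation between genes of the stress list was 0.575. This list was also higher in the double-positive and RFP-only libraries of litter 5 than in the others of their populations (by 1.21 and 0.48), and the double-positive one did not lie apart (SD 1.12 and 1.11, against 1.11). Whether stress is a cause therefore cannot be told apart from a difference shared by litter 5. No other biological explanation was tested.

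Skeletal muscle genes were higher in RFP-only than in GFP-only cells (median 4.35). If all other cell types leaked alike into the gate, the epidermis list should rise too. It had a median of -0.75 but was not called (camera adjusted p = 0.0834). Of its 14 genes 1 rose (Epcam, adjusted p = 0.0476) and 2 fell (Krt8 and Perp). A fold change also depends on the level of these genes in GFP-only cells, so the median cannot decide whether there was such a leak. The medians of the muscle and epidermis lists differed by 5.10 (permutation test over genes, p = 3e-05 of 100000 resamples). That p treats genes as independent and measures their spread, not that between libraries. The estimated correlation between genes was 0.538 in the muscle and 0.182 in the epidermis list. The pericyte, blood, endothelial and erythroid lists were called higher at the preset correlation but not at an estimated one (adjusted p = 0.0016, 0.000425, 0.00105 and 0.0191, but 0.277, 0.488, 0.434 and 0.434 with an estimated correlation), with medians of 2.82, 2.81, 2.18 and 1.54. The erythroid p was 0.0953 without the GFP-only library of litter 1 and 0.0665 without the RFP-only library of litter 2. The Schwann cell and neuron list had members on both sides and was not called (median 1.48, adjusted p = 0.328). A leak of several cell types, with or without epidermis, stays open. Of 19 muscle genes 84.2% (16) had their lowest RFP-only value in litter 1, but that library was chosen by the median of the same genes, so a share of muscle cells that varies between libraries cannot be told apart from other causes. Actc1, an abundant muscle actin gene, had 3648, 15582 and 11448 normalized counts in RFP-only litters 1, 2 and 5. Whether muscle cells express Creb5 themselves was not tested.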
